A study of Homo sapiens with 20 samples.

How the data were processed

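Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in 20 libraries of 7 groups. Per the labels' protocols, MCF10A cells, an immortalised and non-tumorigenic human mammary epithelial line, were grown in alginate gels with reconstituted basement membrane of 100 or 2000 Pa, on polyacrylamide of 100 Pa or on tissue culture polystyrene. Some gels received 1 µM suberoylanilide hydroxamic acid (SAHA), an inhibitor of histone deacetylases. Of the 20 libraries, 18 came from these cultures, 3 per group, and 2 from mammary epithelium in vivo. Groups follow the titles and the stiffness and treatment fields. The descriptions of 2 of the 3 untreated 2000 Pa libraries and of all 3 SAHA-treated 2000 Pa libraries call the gel soft, while their titles, stiffness fields and the peak lists they name give 2000 Pa, which was followed. The source field of the tissue libraries names MCF10A, and the title and description, which say mammary gland, were followed. The polystyrene libraries carry a stiffness of 2000 Pa in the labels. Polystyrene is far stiffer than any of the gels, so this value was not used as a dose.

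The analysis rested on 14 deposited peak lists, 2 per group, and on a list of merged regions for the whole series. One list per group kept peaks by naive overlap and the other by an irreproducible discovery rate (IDR) of 0.1, per the file names. These names also carry the mark ppr, whose meaning is not stated. Whether overlap and IDR compared libraries or parts of one pool is not given. Neither list is therefore taken as agreement between libraries. The descriptions of all libraries of a group name the same lists and call the signal tracks pooled, nodup and tn5, so each list stands for a whole group. All coordinates are on hg19, and bedtools and DESeq2 were used, per the submitters' processing notes. The aligner, the peak caller and their settings are not given in the sources used here. The fold and the −log10 values of p and q given for each peak are the authors' own, as deposited, and describe a summit against the local background of the same pooled library. The deposited score is 10 times the −log10 p as a whole number, at most 1000, in the naive overlap lists, and runs from 413 to 1000 in the IDR lists. Peak values were used to describe, rank or filter peaks within a list and to recover its depth. Between lists, they enter the thinning, the local background by chromosome arm, a check of summit height on chromosome 20, the folds printed for one region in more than 1 list and the number of regions with a fold of at least 5 in 5 cultures that the remaining list lacked. Of the naive overlap lists, 5 of 7 end at a peak rank of about 300000, and whether a limit on the number of peaks was set is not given in the sources used here. The lowest −log10 p was 2.0 in the stiff 3D and plastic lists, 2.19 in the soft 3D list, 2.42 and 3.31 in the soft and stiff 3D lists with SAHA and 2.53 in the soft 2D list, so region numbers as listed rest on different floors.

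The merged region list holds 221510 regions with 3 columns (chromosome, start and end) and 0 columns of counts. It equals the union of the 7 naive overlap lists region by region. Without a value per library there are no replicates to test: the planned count models, correlations between libraries, permutation tests, replicate block and omission of single libraries were not run, and no p-value was computed. No annotation on hg19 was used, so the 18 planned gene lists, the cell type markers, promoter classes and motifs were not analysed here, and regions are named by position and cytogenetic band. Every difference is therefore one between 2 pooled lists, with no replicate check. Exact Clopper-Pearson intervals (95%) are given for shares of regions and cover counting error only.

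A region counted as listed in a group where a peak of that group overlapped it by at least 1 bp. Depth was read from the lists themselves. The deposited fold and −log10 p of a summit fit a Poisson upper tail with a whole-number pileup and a pseudocount of 1, which returned the pileup and the local background of 98.8% to 100.0% of summits per naive overlap list (tolerance 0.0005 in −log10 p). The most frequent background is the genome-wide floor and was taken as relative depth. Local backgrounds above the floor were whole multiples of 0.015 in 100.0% of cases in each of the 7 lists (tolerance 0.001), the step of tags extended to 150 bp and averaged over 10000 bp. For each chromosome arm with at least 20 autosomal regions in all 7 lists, the log2 of local background over the floor was centred on the median of its list before lists were compared.

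To compare lists of different depth, tags were removed at random from both lists of a pair until the background was 75% of the lower of both. Regions whose −log10 p was at least 5 were counted over 20 draws. A region was specific to one list at matched background if it reached 5 there and stayed under 2 in the other, in at least 10 draws. Such a region can still be listed, at a lower −log10 p, in the full list of the other group. Regions called in both lists were taken from the full naive overlap lists, without thinning or the minimum of 5. Their shares therefore rest on another threshold than those of the specific sets. The number of regions specific by this rule can differ from the mean number per draw, and unequally for both lists of a pair. Thinning was chosen after the lists had been seen, as were minimums of 3 and 10 in place of 5 and the counts per 1 Mb window. The SD over draws covers the thinning only. Where specific sets of 2 comparisons were intersected, the number expected of independent sets was taken over regions listed in both comparisons. Set members outside those regions did not enter it. Those regions include weak ones, while specific regions had to reach 5, so the expected number can be too low. Every intersection exceeded it, by 1.32 to 9.59 times. Tested on simulated data of 40000 regions per pair with the depths of the real lists, thinned ratios of region numbers with no difference in signal lay between 0.93 and 1.22 over the 7 pairs, where lists simulated at one depth gave 0.99 to 1.0. Matching the background therefore removes a difference in depth only in part, so the simulated ratios are given beside the thinned ones of pairs. Thinning all 7 lists to one background was not simulated. The simulated lists were simpler than the real ones. Every region had the floor as its background, both lists began at −log10 p of 2, and no overlap or rank filter was applied. In the real naive overlap lists 10.5% to 24.6% of summits lay at the floor. The simulated ratios are therefore a rough guide. The recovery returned the exact pileup of 100.0% of 18652 simulated summits.

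The rule for named regions, fixed before the data were examined, asked for a count test. It was replaced, after the lists had been seen, by a rule on the lists. Regions had to be in both lists of one group and in neither list of the other, and the 12 (stiff against soft 3D gels) or 10 (other comparisons) with the highest deposited fold each way were named. Regions on X were not compared with the tissue, and none on Y was named. Region numbers and shares were also computed from the IDR lists, from peaks with −log10 q of at least 5, and with 50% of a peak required to be covered for sharing, all set before the data were examined. Protein-coding genes per chromosome came from RefSeq names of assembly GRCh38.p14, without coordinates, over chromosome lengths of the hg19 band table. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with cytogenetic bands of hg19 from circlize 0.4.16.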

Results

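The data were ATAC-seq peak lists of 6 MCF10A culture groups and of mammary epithelium in vivo. The cultures were soft (100 Pa) and stiff (2000 Pa) 3D gels, each without and with 1 µM SAHA, a soft (100 Pa) 2D gel and 2D plastic. Each culture group pooled 3 libraries and the tissue 2. In the naive overlap lists, 2D plastic held 44088 regions, the stiff 3D gel 51348, the soft 3D gel 57630, the tissue 80477, the soft 3D gel with SAHA 88478, the stiff 3D gel with SAHA 103036 and the soft 2D gel 105487. Median widths ran from 363 bp in the stiff 3D gel to 533 bp in the tissue. Covered length ran from 22.64 Mb on 2D plastic to 57.43 Mb in the soft 2D gel. Depth differed between the lists. The background pileup, taken as the genome-wide floor, was 1.81 tags on 2D plastic, 4.08 in the soft 3D gel with SAHA, 4.18 in the stiff 3D gel, 6.14 in the soft 3D gel, 6.49 in the soft 2D gel, 6.58 in the stiff 3D gel with SAHA and 9.49 in the tissue. With all 7 lists thinned to a background of 1.36, the soft 3D gel kept 15223 regions, the stiff 3D gel 20801, 2D plastic 29534, the tissue 31989, the stiff 3D gel with SAHA 37953, the soft 2D gel 52020 and the soft 3D gel with SAHA 52213. At this background, simulations covered only plastic against the soft 2D gel and against the stiff 3D gel. How much of the other differences is left over from depth is therefore not known.

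**Figure D1:**
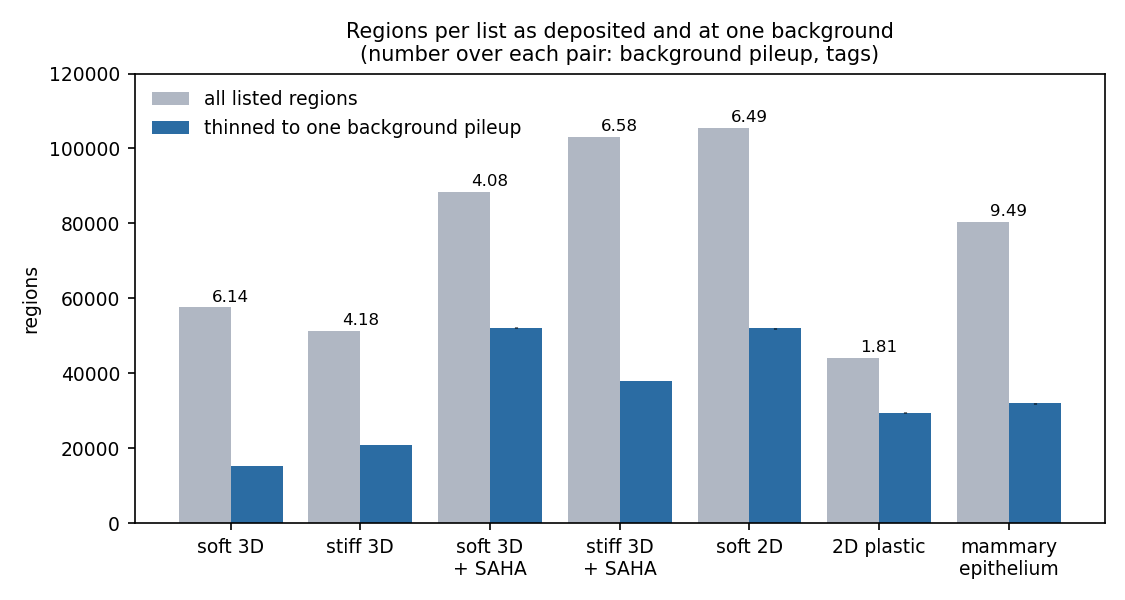
Regions (y axis) per group (x axis), as listed (grey bars) and after thinning to a background of 1.36 tags (blue bars, with SD over 20 draws); the number over each pair is the background pileup of the list. The soft 3D gel held more listed regions than the stiff 3D gel (57630 against 51348) and fewer after thinning (15223 against 20801). Thinning of the soft 3D gel to this background was not simulated.

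The regions fell into classes by how many cultures listed them. A core of 21640 regions, 9.8% of the 221510, was listed in all 6 cultures. These were the widest, with a median of 989 bp, and 71.2% of the autosomal ones (95% interval 70.6% to 71.8%) were also listed in the tissue. Regions in 2 to 5 cultures numbered 70937, with a median width of 584 bp and 32.4% in the tissue. The most numerous class, 96431 regions or 43.5%, was listed in a single culture, was 352 bp wide at the median and had 10.1% in the tissue (10.0% to 10.3%). The soft 2D gel had 28610 such regions, the stiff 3D gel with SAHA 25823 and the stiff 3D gel 6461. Another 32502 regions were listed in the tissue alone, and 15412 were in all 7 lists.

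The main comparison asks how the stiffness of a 3D gel relates to open chromatin in mammary epithelial cells. Soft and stiff gels shared 32233 regions, which was 55.9% of the soft list and 62.8% of the stiff list. As listed, the stiff gel held 0.89 times as many regions as the soft gel. With both lists thinned to a matched background of 3.13 it held 36349 ± 64 regions (SD over 20 draws) against 29052 ± 71, a ratio of 1.25. After thinning 8076 regions were specific to the stiff gel and 3304 to the soft gel. Counted per draw, the means were 8417 and 4556, a smaller contrast, so part of the asymmetry comes from the rule of at least 10 draws. Of the stiff-specific regions 39.3% (38.2% to 40.4%) were also listed in the mammary epithelium, against 31.7% (30.1% to 33.3%) of the soft-specific. Regions in both full lists, which were not thinned, reached 63.6%. Most recurred in other cultures: 72.4% of the stiff-specific regions were listed in the soft 3D gel with SAHA, 73.7% in the stiff 3D gel with SAHA, 77.6% in the soft 2D gel and 31.1% on 2D plastic. Soft-specific regions recurred to a similar extent, at 71.5%, 70.7%, 74.0% and 33.4%. No other culture listed 11.9% of the stiff-specific and 14.1% of the soft-specific regions.

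**Figure D2:**
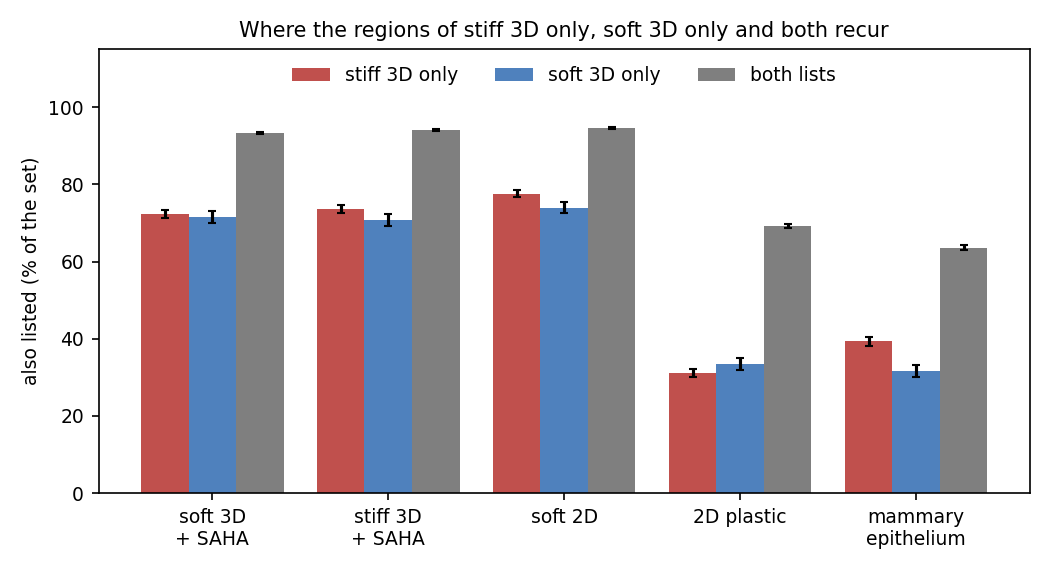
Share of a set of regions that was also listed in a further group (y axis, percent) for 4 other cultures and the tissue (x axis); bars are regions specific to the stiff 3D gel (red), specific to the soft 3D gel (blue) and in both lists (grey), with exact 95% intervals. In the tissue the stiff-specific set reached 39.3% and the soft-specific set 31.7%. The specific sets were taken after thinning and the grey set from the full lists.

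Among the 2854 regions in both lists of the stiff gel and neither list of the soft gel, the 12 with the highest deposited fold ran from 7.5 to 9.9. The first, at 10q24.1 (chromosome 10, 98561374 to 98561624, hg19), had a fold of 9.9 and was in no other culture. The other 11 were all also listed in both SAHA-treated gels and the soft 2D gel. They included 12p12.3 (chromosome 12, 15599784 to 15600171, fold 8.7), 2q31.3 (chromosome 2, 181521230 to 181521642, fold 8.3) and 9q33.1 (chromosome 9, 121081051 to 121081747, fold 8.3), which the tissue lacked. The regions at 17q24.2 (chromosome 17, 66243492 to 66244864, fold 8.7) and 5q14.1 (chromosome 5, 79950273 to 79951062, fold 8.0) were also in the tissue. In the other direction 2017 regions qualified, and the leading 12 ran from a fold of 6.6 to 31.0. All 12 were listed in the other 4 cultures as well, so each was missing from the stiff gel alone. They were led by 1q24.2 (chromosome 1, 169443230 to 169443466, fold 31.0), 3p14.1 (chromosome 3, 68708136 to 68708352, fold 18) and 12q23.3 (chromosome 12, 107421102 to 107421900, fold 9.8).

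Stiff-specific regions were densest in the 1 Mb window at 14q32.33 (chromosome 14, 106000001 to 107000000), the band of the immunoglobulin heavy chain genes, with 17 regions against 2 soft-specific. Windows at 8p12 (15 against 6), at 1q21.3 (14 against 3) and at 10q23.31 (14 against 1) followed. The soft-specific set had its densest window at 9q31.3, with 8 regions against 8 stiff-specific. The direction of the difference in region number changed with the processing: the IDR lists gave 1.07 and peaks with −log10 q of at least 5 gave 1.04, against 0.89 for all listed regions. In simulated lists of 40000 regions with these 2 depths the thinned ratio was 1.05 with no difference in signal and 1.3 with a 1.2-fold gain. The track names of the stiff gel alone lack the mark PE2SE, whose meaning is not stated. Stiffness therefore cannot be separated here from what that mark records.

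SAHA was added to ask how inhibition of histone deacetylases relates to open chromatin at each stiffness. At 100 Pa the treated list held 88478 regions against 57630 untreated, a ratio of 1.54. At matched background it held 72227 ± 77 against 28514 ± 64, a ratio of 2.53, where simulated lists with no difference in signal gave 1.06. The untreated regions were largely kept: 64.2% of them were in the treated list, and 89.5% at matched background. The treated gel had 37799 specific regions at matched background and the untreated gel 1435. Counted per draw, the means were 37948 and 2594. Of the treated-specific regions 68.9% were listed in the stiff gel with SAHA and 67.6% in the untreated soft 2D gel, but 21.4% in the untreated stiff 3D gel and 28.7% in the tissue. Dark Giemsa bands, which are late-replicating and gene-poor, held 25.7% of them (25.2% to 26.1%), against 19.4% of the regions in both lists. For the untreated soft 2D gel compared with the untreated soft 3D gel, they held 26.9% of the soft 2D-specific regions and 19.6% of those in both lists. The excess was therefore not particular to SAHA.

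At 2000 Pa the treated list held 103036 regions against 51348, a ratio of 2.01. At matched background the numbers were 62924 ± 93 and 36363 ± 52, a ratio of 1.73 against a simulated one of 0.93. The treated gel had 26487 specific regions, of which 75.4% were listed in the soft gel with SAHA, 69.6% in the soft 2D gel, 19.4% in the untreated soft 3D gel and 26.8% in the tissue. Dark bands held 27.1% of them (26.6% to 27.7%), against 20% of the regions in both lists. The untreated gel had 3236 specific regions, of which 30.1% were in no other culture. Between the stiffnesses, 14668 treated-specific regions were the same, 38.8% of those at 100 Pa. This was 1.87 times the 7859 expected of independent sets, taken over 26988 and 20575 set members among 70658 regions listed in both comparisons. The regions specific to the untreated gels shared 207, where 22 were expected in the same way. The expected numbers can be too low because weak regions enter them, so no agreement between stiffnesses is read from either excess.

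At 100 Pa, 17777 regions were in both lists of the treated gel and neither list of the untreated gel. The 10 with the highest folds, from 16.9 to 19.1, included 6q24.3 (chromosome 6, 146432901 to 146433415, fold 19.1), 4q22.1 (chromosome 4, 90645781 to 90646228, fold 18.4) and 12q21.32 (chromosome 12, 87534076 to 87534419, fold 17.7). These 3 were listed in neither untreated 3D gel but in the soft 2D gel. At 2000 Pa, 16427 regions qualified. The leading 2, at 1q24.2 and 3p14.1 with folds of 30.0 and 25.1, were those missing from the untreated stiff gel alone. They were followed by 6q22.33 (chromosome 6, 129253195 to 129253737, fold 15.3). The region at 2p15 (chromosome 2, 63764401 to 63764936) was named at both stiffnesses, with folds of 17.5 at 100 Pa and 14.0 at 2000 Pa. Like the region at 6q22.33, it was also listed in both untreated 2D cultures, so only the untreated 3D gels lacked it. Every region named for the treated gels at either stiffness was also listed in the untreated soft 2D gel. In the other direction 970 regions qualified at 100 Pa and 966 at 2000 Pa. They were led by 13q13.2 (chromosome 13, 34639938 to 34640936, fold 7.3) at 100 Pa and 11p12 (chromosome 11, 39033300 to 39033794, fold 10.6) at 2000 Pa. Treated-specific regions at 100 Pa were densest at 5q31.3 (40 against 1 in the window from 141000001 on chromosome 5) and at 1q32.1 (38 against 2). At 2000 Pa they were densest at 1p31.3 (31 against 1). Windows were ranked by number alone: over all comparisons 39 of the 70 densest lay on 1q, 5q, 8q, 20p or 20q, the 5 arms where the local background of the cultures was highest against the tissue. The track names of both treated lists are of another style than those of the untreated 3D lists and of the same style as those of the 2D lists. Treatment therefore cannot be separated from whatever that style records. At 2000 Pa the untreated list also lacks the mark PE2SE, from which treatment cannot be separated either.

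Under SAHA, the 2 stiffnesses shared 63840 regions, 72.2% of the soft list. The Jaccard index (shared over listed in either) was 0.5, against 0.42 for the untreated gels, and 0.609 against 0.544 at matched background. The share of soft regions also in the stiff list went the other way at matched background, at 70.3% with SAHA and 79.3% without, so no direction can be read for the overlap. The stiff gel held 1.16 times as many listed regions. At matched background it held 61895 ± 103 against 72210 ± 60, a ratio of 0.86 (simulated with no difference in signal, 0.93). Counted per draw, on average 9311 regions were specific to the stiff and 13768 to the soft gel. By the rule of at least 10 draws the sets held 7154 and 13379. Of these sets 39.8% and 44.6% were in no other culture. The stiff-specific sets without and with SAHA had 341 regions in common, 4.2% of the untreated set, where 217 would be shared by independent sets. The expected number rests on 6606 of the 8076 untreated and 1699 of the 7154 SAHA-treated regions, those listed in both comparisons. The stiff-specific regions under SAHA were led by 2q24.2 (chromosome 2, 160998476 to 160999386, fold 9.0), listed also on 2D plastic and in the tissue. The soft-specific were led by 5p12 (chromosome 5, 45454118 to 45454578, fold 14.8). The soft-specific set was densest at 12q13.13, the band of the type II keratin and HOXC gene clusters, with 18 regions against 3 and 16 against 1 in adjoining windows, and at 6p22.2, a band of clustered histone genes, with 18 against 3. Thinned ratios of stiff to soft were thus 0.86 with SAHA and 1.25 without, a ratio of ratios of 0.69. As listed, the ratio of ratios was 1.3, and with the IDR lists it was 0.94. None of these was tested. The mark PE2SE is missing for the untreated stiff gel alone, so what it records does not cancel in them.

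**Figure D3:**
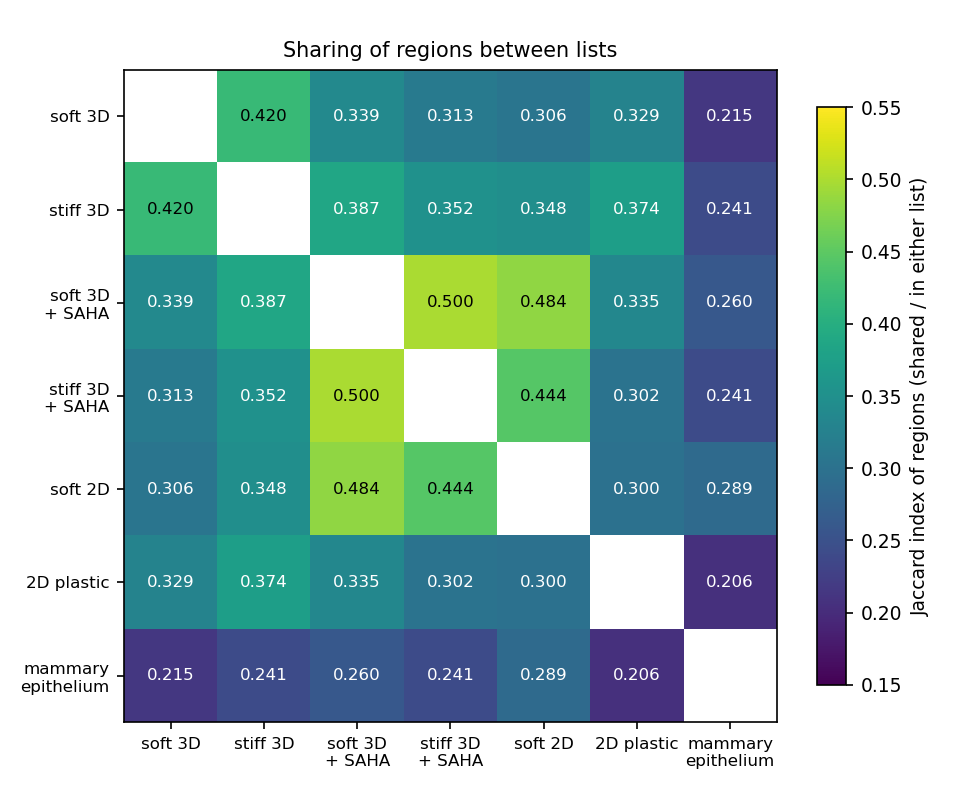
Jaccard index of regions for the 21 pairs of the 7 naive overlap lists (both axes list the groups; colour and printed number give the index). The pair of SAHA-treated gels had the highest index (0.5), the soft 2D gel with the soft SAHA-treated gel had 0.484, and pairs with the tissue lay between 0.206 and 0.289.

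The 2D cultures extend the comparison of stiffness to cells on a flat substrate. Plastic and the polyacrylamide gel differ in material as well as in stiffness, and these cannot be separated here. Plastic and the soft 2D gel shared 34538 regions, which was 78.3% of the shorter plastic list and 32.7% of the soft 2D list. Plastic held 0.42 times as many listed regions. At matched background it held 29546 ± 53 against 52007 ± 114, a ratio of 0.57. The soft 2D gel had 22278 specific regions, of which 47.0% were in the tissue and 72.8% in the soft 3D gel with SAHA. Plastic had 2130, of which 14.2% were in the tissue and 42.2% in no other culture. Regions on plastic lay more often in dark bands, at 32.1% (30.1% to 34.2%) of the plastic-specific set against 21.2% (20.6% to 21.7%) of the soft 2D-specific set. The 28668 regions in both soft 2D lists and neither plastic list were led by 1q32.1 (chromosome 1, 206137957 to 206138470, fold 31.0) and 12q12 (chromosome 12, 38710127 to 38711037, fold 23). Both were in the other 4 cultures and in the tissue. The 529 in the other direction were led by 7q34 (chromosome 7, 141504940 to 141505218, fold 16.8), which no other culture listed. Soft 2D-specific regions were densest in windows at 1q32.1 (41 against 3), 11q13.1 (41 against 0) and 19q13.33 (40 against 0). Simulated lists of these depths gave a thinned ratio of 1.22 with no difference in signal. The plastic list is the shallowest, with a background of 1.81.

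The thinned ratio of plastic to the soft 2D gel (0.57) over that of the stiff to the soft 3D gel (1.25) was 0.46, which was not tested. What the mark PE2SE records, missing for the stiff 3D gel alone, does not cancel in it. The stiff-specific sets of 3D and 2D had 81 regions in common, where independent sets would share 62. The soft-specific sets had 813 in common, where independent sets would share 580. Of the 2D sets, 474 of the 2130 plastic-specific and 11373 of the 22278 soft 2D-specific regions entered these expected numbers.

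Cells at the same 100 Pa on a 2D gel and in a 3D gel shared 38247 regions, which was 66.4% of the soft 3D list and 85.2% at matched background. The Jaccard index, which falls with the length of the longer list, was 0.306. The soft 2D list held 1.83 times as many regions as the soft 3D list. At matched background it held 87464 ± 57 against 36455 ± 56, a ratio of 2.4, where simulated lists with no difference in signal gave 0.99. The soft 2D gel had 51763 specific regions, of which 51.2% were in the soft 3D gel with SAHA and 32.0% in the tissue. Dark bands held 26.9% of them (26.5% to 27.3%), against 19.6% of the regions in both lists. The soft 3D gel had 4295, of which 54.9% were in no other culture and 11.9% in the tissue. The leading soft 2D regions were 16p13.11 (chromosome 16, 15247986 to 15249063, fold 20.6) and 8q12.3 (chromosome 8, 62991322 to 62991923, fold 19.6). Both were also in the stiff 3D gel and in both SAHA-treated gels. Those missing from the soft 2D gel were led by 2q36.3 (chromosome 2, 228806835 to 228807094, fold 7.3) and 3q29 (chromosome 3, 196264369 to 196265028, fold 6.9). Soft 2D-specific regions were densest at 1q22 (52 against 4), 3p13 (51 against 1) and 8q24.22 (51 against 2). The material differs too, polyacrylamide in 2D and alginate with basement membrane in 3D, so dimension cannot be separated from it. The style of the track names also goes together with dimension here, as for SAHA.

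Plastic and the stiff 3D gel had a Jaccard index of 0.374. Plastic held 0.86 times as many listed regions and, at matched background, 29540 ± 58 against 20852 ± 60, a ratio of 1.42. Plastic had 7933 specific regions, of which 35.1% (34.1% to 36.2%) lay in dark bands and 30.5% were in the tissue. The stiff 3D gel had 4075, of which 11.5% (10.6% to 12.5%) lay in dark bands, 60.3% were in the tissue and 73.8% were in all other cultures. The stiff 3D regions were led by 14q21.3 (chromosome 14, 50582818 to 50583849, fold 13.3) and 1p36.11 (chromosome 1, 27003794 to 27004533, fold 12.3). The densest windows were 19p13.3 for the stiff 3D gel (21 against 1) and 1q43 for plastic (20 against 1). The plastic regions were led by the same 1q24.2 region as above, with a fold of 47.3. Simulated lists of these depths gave a thinned ratio of 1.16 with no difference in signal, and the direction as listed was opposite to that at matched background. The track names of both lists also differ in style and in the mark PE2SE, so substrate cannot be separated from what these record.

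The tissue served as the in vivo reference for the cultures. Over the autosomes, 49.9% (49.4% to 50.3%) of the stiff 3D regions and 42.5% (42.1% to 42.9%) of the soft 3D regions were listed in the tissue. The shares were 48.4% on plastic, 39.6% in the soft 2D gel, 39.6% in the soft 3D gel with SAHA and 34.7% in the stiff 3D gel with SAHA. Seen from the tissue, the soft 2D gel covered the most of its regions, 51.7%, followed by the stiff (44.1%) and soft (43.2%) 3D gels with SAHA. The stiff 3D gel covered 31.8%, the soft 3D gel 30.4% and plastic 26.3%. At matched background the soft 2D gel again covered the most, 61.5%, and the soft 3D gel the least, 27.3%. Thinning does not make the lists equally long: the soft 2D gel kept 50706 autosomal regions and the soft 3D gel 14990. Shares of the culture regions ran the other way there. In the tissue were 57.1% of the soft 3D, 55.0% of the stiff 3D and 38.0% of the soft 2D regions. Which culture is nearest to the tissue cannot be read from either share. The difference of 7.4 points between stiff and soft 3D gels thus changed sign, to -2.1. Thinning of the soft 3D gel and the tissue to this background was not simulated, so an effect of the thinning itself cannot be told apart.

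The local background of the summits, which follows the number of tags per 10000 bp around them, was also compared along the chromosomes over the 15046 autosomal regions in all 7 lists. On both arms of chromosome 20 it was higher in the untreated 3D gels than in the other 4 cultures, by 0.21 on the log2 scale on 20p and 0.35 on 20q. The other 37 arms lay between -0.11 and 0.19, with an SD between arms of 0.07. Relative to the mean of the 6 cultures, 20q stood at 0.20 in the soft 3D gel, 0.25 in the stiff 3D gel, -0.12 in the soft and -0.07 in the stiff 3D gel with SAHA, -0.09 in the soft 2D gel and -0.17 on plastic. On 20p the values were 0.17 in the soft and 0.10 in the stiff 3D gel. In the stiff 3D gel 20p did not stand out, since arms such as 19p (0.22), 22q (0.19) and 17q (0.17) were higher. Chromosome 20 held 3.92% of the regions of the soft 3D gel and 3.58% of those of the stiff 3D gel, against 2.96% and 3.04% with SAHA. It therefore moves together with the comparisons of untreated 3D gels with SAHA-treated gels and with 2D cultures, while soft and stiff 3D gels lay within 0.07 of each other on both arms.

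**Figure D4:**
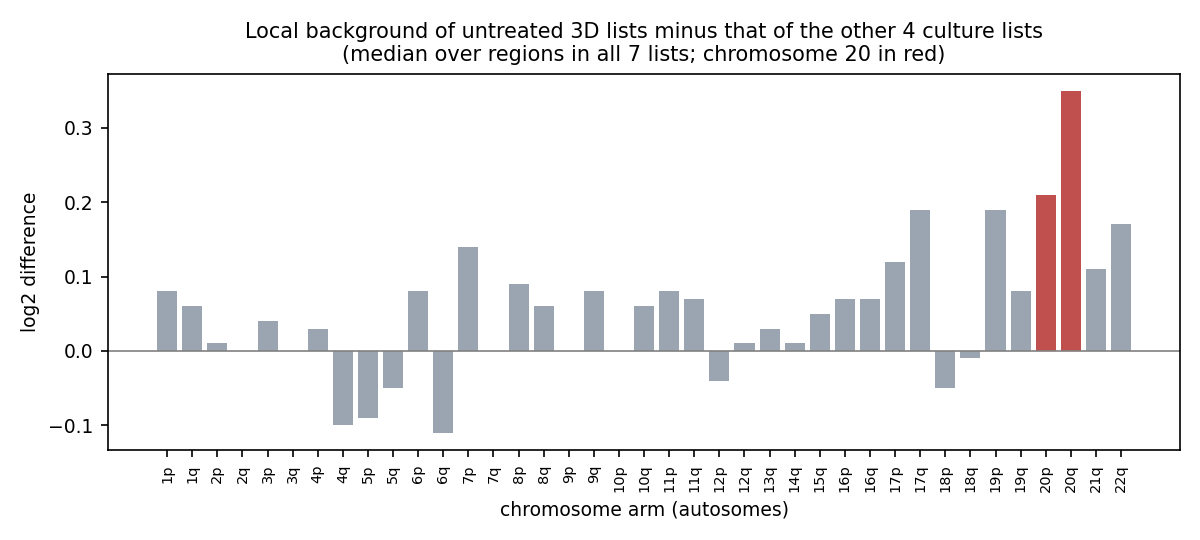
Local background of the 2 untreated 3D lists minus that of the other 4 culture lists (y axis, median log2 difference over regions in all 7 lists) for 39 autosomal arms (x axis), with chromosome 20 in red. The arms 20p (0.21) and 20q (0.35) stand above the highest of the other arms (0.19).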

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

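All 3 tests described here, and the thinning to one background on which they rest, were chosen after the results were seen. The ratio of region numbers between stiff and soft 3D gels stood on opposite sides of 1 with and without SAHA. At matched background the stiff gel held 0.86 times as many regions as the soft gel with SAHA and 1.25 times as many without it, a ratio of 0.69, and the difference was not tested because each group is a single pooled list. The direction was not stable: the ratio of ratios was 1.3 as listed, 0.94 with the IDR lists, 0.99 with −log10 q of at least 5 and 0.94 with a minimum of 3. Simulated lists with no difference in signal gave 0.93 with SAHA and 1.05 without, on the same sides of 1. Only the untreated stiff 3D gel lacks the mark PE2SE in its track names, so what that mark records does not cancel in this ratio of ratios. In 2D and 3D cultures the ratios at matched background also lay on opposite sides of 1, though as listed both lay below it (0.42 and 0.89): plastic held 0.57 times as many regions as the soft 2D gel, against 1.25 for stiff over soft 3D gels, a ratio of 0.46, which was likewise not tested. Here the stiffness of plastic is not that of the stiff gel, and the shallowest list is one of those compared. Plastic also differs from the soft 2D gel in material, and the missing mark PE2SE of the stiff 3D gel enters this ratio too.

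The soft 3D gel listed more regions than the stiff 3D gel, at 57630 against 51348. Its background pileup was also higher, at 6.14 against 4.18 tags. With both lists thinned to one background the order turned to 1.25 in favour of the stiff gel, so greater depth is a candidate explanation of the longer soft list. What stays open is whether the excess in the stiff gel at matched background comes from the gel: the same simulated depths gave 1.05 with no difference in signal and 1.3 with a 1.2-fold gain, so a small difference in library quality could have this size. The track names of this gel alone also lack the mark PE2SE, and stiffness cannot be separated from what that mark records. The stiffness of the gel stays among the open explanations, without a replicate to test it.

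SAHA-treated gels listed more regions than untreated gels at both stiffnesses. Depth is argued against, since the smaller of both ratios at matched background was still 1.73, where simulated lists with no difference in signal gave 0.93. Another run or cell stock than that of the untreated 3D libraries cannot be told apart from the treatment: the untreated soft 2D gel, whose track names are of the same style as those of the SAHA lists, also held 2.4 times as many regions as the untreated soft 3D gel. The treated-specific regions recur in that untreated 2D culture, at 67.6% for 100 Pa and 69.6% for 2000 Pa, but so do the untreated-specific ones, at 55.2% and 54.3%, and its list is the longest. The local background of 20q also set both untreated 3D lists (0.20 and 0.25) apart from the SAHA and 2D lists (-0.17 to -0.07), for a cause that stays open. At 2000 Pa the untreated list also lacks the mark PE2SE, whose meaning is not stated. An effect of SAHA on chromatin stays open and may act together with a difference of run or cell stock.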

How the results depend on the processing

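Thinning to one background and its minimums of 3 and 10 for −log10 p were chosen after the data were seen, and the other settings before. Direction was kept under every setting run for 5 of the comparisons of cultures, with and without SAHA at both stiffnesses, plastic with the soft 2D gel, the soft 2D with the soft 3D gel and the 2D with the 3D relation, but some values moved by over 1.5 times. The ratio of stiff to soft 3D gels, 0.89 as listed, turned to 1.07 with the IDR lists, 1.04 with −log10 q of at least 5, 1.25 at matched background, 1.07 with the minimum of 3 and 1.46 with the minimum of 10. Under SAHA the ratio of stiff to soft, 1.16 as listed, turned to 0.86 at matched background and 0.68 with the minimum of 10. Plastic over the stiff 3D gel, 0.86 as listed, turned to 1.42 at matched background, 1.14 with the minimum of 3 and 2.04 with that of 10. The ratio of ratios with and without SAHA, 1.3 as listed, turned to 0.94 (IDR), 0.99 (−log10 q), 0.69 (matched background), 0.94 (minimum of 3) and 0.47 (minimum of 10). SAHA at 100 Pa, 1.54 as listed, moved to 2.53 at matched background and 3.96 with the minimum of 10. The soft 2D over the soft 3D gel, 1.83 as listed, moved to 2.8 with −log10 q of at least 5 and 3.25 with the minimum of 10. The 2D relation over the 3D one, 0.47 as listed, moved to 0.28 with −log10 q of at least 5. The difference between stiff and soft 3D gels in the share found in the tissue, 7.4 points, moved to 0.6 (IDR) and 1.2 (−log10 q) and turned to -2.1 at matched background. For each of these changes the cause was not tested, since matching the background removes a difference in depth only in part. Of the values above and their alternatives, 16 reversed, 7 moved and 25 stayed within 1.5 times. All 46 alternatives to shares of regions moved by more than the exact interval, which is narrow at these numbers.

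No paired analysis was possible because each list pools the libraries of a group and no value per library was analysed here. For the same reason the 7 alternatives set for each comparison of cultures were not run: no scaling, a loess offset, DESeq2, no low-count filter, only the groups compared, the replicate block and leaving out each replicate. Correlations with the tissue, promoter gene lists and motifs were not run either. Depth limits weak regions most. The plastic list, with a background of 1.81 tags, cannot show many regions that a list at 6.49 can, so absence from it is not absence of accessibility.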

Other observations

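Of the tests on chromosome 20 described here, those on gene density and on the number of copies were chosen after the result was seen. Single windows and regions were picked out after their values were seen. The 1 Mb window at 14q32.33, the band of the immunoglobulin heavy chain genes, held 33 regions in the stiff 3D gel and 30 in the soft 2D gel. It held 12 in the soft 3D gel, 10 and 14 in the soft and stiff 3D gels with SAHA and 5 on plastic. Of those in the stiff 3D gel 21, and of those in the soft 2D gel 16, were in no other culture. The window from 142000001 on chromosome 7 at 7q34, the band of the T cell receptor beta genes, held 62 regions in the soft 2D gel. It held 38 and 31 in the stiff and soft 3D gels with SAHA, 19 on plastic, 12 in the soft 3D gel and 8 in the stiff 3D gel. At 17q21.2, the band of the type I keratin genes, the window from 39000001 on chromosome 17 held 56 regions in the soft 2D gel, 48 in the soft 3D gel with SAHA, 42 in the stiff 3D gel with SAHA, 41 in the soft and 32 in the stiff 3D gel, and 13 on plastic.

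The run with the most neighbouring regions that the tissue listed and no culture did lay at 9p21.3, where MCF10A is known to carry a deletion that includes CDKN2A. It held 9 tissue regions between 21964783 and 22103624 on chromosome 9, and no culture listed a region between 21854968 and 22158969, a gap of 304.0 kb. Another 5 runs held 8 tissue regions each, among them 5q14.3 (chromosome 5, 88120786 to 88238915) and 1p36.22 (chromosome 1, 10758866 to 10787108). Against the tissue, the local background of the 6 cultures was highest on 1q, by 0.69 on the log2 scale, then on 5q (0.36), 8q and 20q (0.29 each) and 20p (0.19). MCF10A is known to carry gains on 1q, 5q, 8q and 20.

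The background of chromosome 20 was higher in both untreated 3D lists than in the other 4 cultures, with a median difference of 0.30 on the log2 scale over 412 regions, or 1.23-fold, and its share of the listed regions was larger in these lists (3.92% and 3.58%) than in the other cultures (2.63% to 3.05%). A trend with gene density across chromosomes is argued against, since chromosome 20 lay 4.6 residual SDs above the line through the other autosomes. More open regions rather than more copies cannot be told apart from more copies. The same difference taken for the height of summits over their local background was 0.01 (log2) above the median of the other autosomes. The rule written before the result was seen would have counted so small a value against more open regions. That rule was not followed, because dividing by the background cancels what open regions nearby would add to it. By the rule set beforehand, the 5 Mb windows did not decide between a single locus and the whole chromosome: 76.9% (10 of 13) showed over 50% of the difference. So many separate windows argue against a single locus, but do not tell a part of the chromosome from all of it. Both arms were raised by at least 2.3 SDs between arms. This restates the pattern for which chromosome 20 was picked, so it decides nothing. On 20p the difference was 0.21, against 0.19 on 17q and on 19p. More copies of chromosome 20, or of a part of it, in the untreated 3D cells stay a hypothesis beside more open regions. No biological explanation tied to a group was tested.

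On plastic the local background was lowest on the gene-rich arms 19p (-0.34), 19q (-0.30), 16p (-0.24), 17p (-0.24) and 22q (-0.24), relative to the mean of the cultures. In the stiff 3D gel it was raised on 19p (0.22), 22q (0.19) and 17q (0.17). Dark Giemsa bands held 25.0% of the regions on plastic, 23.1% in the soft 2D gel, 22.6% and 23.1% in the soft and stiff 3D gels with SAHA, 20% and 19.8% in the soft and stiff 3D gels and 19.8% in the tissue.

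Some regions with a deposited fold of at least 5 in each of 5 cultures were missing from the list of the remaining one. They numbered 516 for plastic, 148 for the soft 3D gel, 44 for the stiff 3D gel, 1 for the stiff 3D gel with SAHA and 0 for both other cultures. Of the 44, the region at 1q24.2 had folds from 30.0 to 47.3 in the other 5 lists, that at 3p14.1 from 18 to 42.2, that at 2q36.3 (chromosome 2, 227586914 to 227587441) from 9.0 to 42.5 and that at 4q22.1 (chromosome 4, 93623048 to 93623282) from 7.4 to 32.9. The track names of the stiff 3D gel alone lack the mark PE2SE. Of the regions missing from the stiff 3D gel 5 of 44 were narrower than 300 bp, against 1 of 148 for the soft 3D gel and 3 of 516 for plastic.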
